A study of Arabidopsis thaliana with 3 samples.

How the data were processed

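RNA of whole Arabidopsis seedlings was hybridised to 3 two-colour Agilent arrays, 2 for fe-1 against wild type and 1 for 35S::FE-GR with Dex against mock. Per the labels' protocols, plants grew in long days at 22 °C with 1% sucrose, and labelled cRNA was made from 0.1 µg of total RNA per channel. The labels put fe-1 and Dex RNA in Cy5 and wild-type and mock RNA in Cy3 on every array, with no dye swap. Groups were taken from the sample titles and source names, and the labels call the fe-1 arrays biological replicates.

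The deposited scanner files hold spot intensity values for each channel, made with Agilent Feature Extraction 10.7.3.1 per the file headers, and the submitters' processing notes name version 10.7. Used here were the median spot intensity and the median local background, which carry no normalization. The files also hold processed signals that the scanner software had background-subtracted, detrended and dye-normalized per the file headers, and their log10 ratio of Cy5 over Cy3, deposited per spot. That log10 ratio was 0 in 13.5% to 15.0% of gene spots. The series value table deposited by the authors holds log2 ratios of Cy5 over Cy3 that differed from the scanner's log10 ratios, converted to log2, by at most 0.005 on any array, with a median of 0 in each column, so its scale, centring and direction are known. No step after the scanner software is given in the sources used here.

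Background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, followed by loess within each array with control spots and outlier spots at weight 0. The design written before the data were examined named mean spot signals, but the files hold medians, which were used instead. On fe-1 replicate 1, 32 gene spots had a local background that the scanner flagged as non-uniform, and they pulled the fitted normexp background mean to -1128 in Cy5 and -317 in Cy3, against -11.4 and -4.02 on replicate 2. The design as written kept these spots, and with them 7 genes were called higher and 44 lower in fe-1. They were left out before normexp, a choice made after seeing the data, after which the means were -10.8 and -3.81. Over the 43803 gene spots of an array, 8 to 43 were left out in all, and 0 were saturated.

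Spots of a probe were averaged, giving 43603 probes. The accessions of 34285 probes matched a locus in a RefSeq gene table (assembly TAIR10.1) without versions, which gave 25383 loci, and 9318 probes were not matched. The table was used only for names and gene order. The array annotation names an older build, so no coordinates are given. A probe was kept in fe-1 if well above background in at least 2 of the 4 channels, and on the Dex array in at least 1 channel. Each gene was read from its brightest kept probe. In fe-1, 6165 genes had over 1 kept probe, and other probes of a named gene can read differently, which the text gives for some genes only. Where a gene was not well above background in every sample of a group, the fold is a lower bound. It is the bright group's mean over the higher of the dim probe's own signal and the lowest signal among probes well above background, per channel after loess and, in fe-1, Aquantile scaling. Such bounds hold for the probe read and the reported processing only, and they are open to dye bias, since no dyes were swapped.

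For fe-1, lmFit and eBayes tested the log2 ratio against 0 on 2 arrays (1 residual degree of freedom, 6.58 prior degrees of freedom), with Benjamini-Hochberg adjustment over 20680 genes and an adjusted p under 0.05 as the threshold. The median SD between the arrays was 0.052. The labels do not say how far apart the replicates were grown, so the p-values measure the spread of these samples only. The 19 gene lists (330 members, 320 tested in fe-1) were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the lists. Estimated-correlation camera and fry were alternatives, and with 1 residual degree of freedom neither called a list. For photosynthesis the estimated correlation was negative (-0.041), yet the unadjusted camera p rose from 0.000541 to 0.162. The estimated-correlation p-values therefore carry little weight for or against a shift. With the preset correlation, camera p-values rest on the spread across genes and do not measure that between the 2 arrays. Estimated correlations of the other called lists were 0.38 (touch), 0.20 (root markers), 0.14 (floral promoters and seed storage), 0.067 (heat shock) and -0.055 (salicylate defence). Where the true correlation exceeds 0.01, the preset test is too lenient. On the Dex array, list medians were set against 10000 random lists of the same size matched on brightness in 50 bins, as a description of that array. The list members TOE1 and TCH3 had no matched probe. The root list member AT1G62500 is named by its locus.

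Named genes followed a rule fixed before the data were examined. It took FE, FT, FTIP1, TSF, CO, SOC1, FLC, SVP and GI, and from each list up to 4 members that passed in fe-1 with the largest ratios and up to 2 at least 2-fold different with Dex. It also took the 10 largest changes per direction in fe-1 (past the threshold and at least 2-fold on both arrays) and with Dex, and up to 10 fe-1 genes moving opposite with Dex. A gene in several parts of the rule is described once. Lists of root hair, inner root and phosphate starvation genes were added after the data had been seen.

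The steps were tested on simulated data: spots of 20680 genes, of which 200 were changed, passed through the same background, loess and test steps. With additive spot noise of SD 1, 98.0% of 2-fold, 76.0% of 1.5-fold and 16.0% of 1.2-fold changes were recovered, and 7.05% of calls were false. The real prior of 6.58 degrees of freedom lay between those of SD 1 (5.32) and SD 2 (9.47). With noise of SD 2 and SD 3, 16.7% and 23.3% of calls were false. The simulation held no dye or slide effect of single probes shared by both arrays, and far fewer changed genes than were called in the data. Its false shares therefore do not describe the real calls. A 2-fold change came out at 0.90 on the log2 scale with SD 1. Alternatives covered the background step, loess, the dim-probe filter, the probe rule, the variance model, thresholds, and leaving out each fe-1 array. Slide as a block was not run, since both fe-1 arrays share a slide.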

Results

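The data were 3 two-colour Agilent expression arrays of Arabidopsis thaliana whole seedlings on day 7. On each array the Cy5 and Cy3 channels held RNA of 2 different samples. Wild type was the Ler accession, and fe-1 is a mutant of FE (AT1G79430, also called ALTERED PHLOEM DEVELOPMENT), which encodes a Myb-related transcription factor of the phloem. The fe-1 comparison had 2 arrays, each a biological replicate with fe-1 RNA in Cy5 and wild-type RNA in Cy3, from seedlings collected at zeitgeber time 15 h. The third array compared 35S::FE-GR (#5) seedlings treated with 1 µM dexamethasone (Dex) for 2 h, in Cy5, with mock-treated seedlings of the same line, in Cy3, at zeitgeber time 14 h. FE-GR is FE fused to the glucocorticoid receptor's hormone-binding domain, which keeps a fusion protein out of the nucleus until Dex is added. Spots well above background made up between 72.1% and 74.8% of the Cy5 channel and between 75.1% and 78.1% of the Cy3 channel. The number of arrays limits the precision. All ratios below are fe-1 over wild type or Dex over mock, on the log2 scale unless a fold is named, with ± for the SD of 2 arrays. The Dex comparison had no replicate, so its values have no error and no test.

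The fe-1 arrays address which transcripts depend on FE. The genes lowest in fe-1 included ALDH10A8 (AT1G74920), a betaine aldehyde dehydrogenase, and a group of neighbouring genes on chromosome 1. AT1G67865 fell by 3.84 ± 0.19 (limma adjusted p = 2.36e-07), although its other probe read -1.48. ALDH10A8 fell by 3.56 ± 0.045, which is 11.8-fold (adjusted p = 1.00e-07). AT1G67860 (-2.91 ± 0.025), AT5G18600 (-2.89 ± 0.26), AT2G32870 (-2.74 ± 0.081) and AT1G64360 (-2.72 ± 0.12) followed. Of these, AT1G67865, ALDH10A8, AT1G67860 and AT1G64360 lie among the 1637 tested genes near FE, so linked differences may contribute to them. AT2G32550 (-2.35 ± 0.19) and AT3G01340 (-2.15 ± 0.033) also fell, and the seed storage genes CRU3 and CRA1, given with their list, completed the 10 largest decreases. AT3G56210 had the largest increase, 2.81 ± 0.12 or 6.99-fold (adjusted p = 3.49e-07), but its 3 probes disagreed and the lowest read 0.03. The sugar transporter gene SWEET4 (AT3G28007) rose by 1.71 ± 0.25, AT1G49570 by 1.68 ± 0.071, AT3G05950 by 1.58 ± 0.12, AT5G10625 by 1.44 ± 0.14 and AT3G46080 by 1.23 ± 0.11. The other large increases were AT2G32210 (1.19 ± 0.037), the cysteine protease gene CP1 (AT4G36880, 1.18 ± 0.14), BGLU25 (AT3G03640, 1.18 ± 0.030) and AT2G32190 (1.13 ± 0.0032).

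Over all 20680 genes tested, 1854 were higher and 2353 lower in fe-1 at a limma adjusted p under 0.05, each of them with the same sign on both arrays. Most differences were small: 3904 of the 4207 called genes changed by under 1.5-fold. On both arrays, 11 genes were at least 2-fold higher and 54 at least 2-fold lower. The log2 ratios of the replicate arrays correlated across genes with r = 0.794 and rho = 0.681, and genes are not independent replicates. These counts leave out the 32 spots with a non-uniform local background on replicate 1, a choice made after the data had been seen. They are called debris spots below, although the cause of the flag was not tested. The background fit as planned before the data were examined kept those spots, and it called 51 genes, 7 higher and 44 lower. Of the 115 named genes called here, 6 were also called in that fit, 49 with the scanner's processed signals and 0 in the series value table, so the adjusted p-values of named genes hold for the reported processing. With the scanner's processed signals, 161 genes were higher and 629 lower, so that the higher genes were 20.4% of the calls instead of 44.1%. The series value table gave 0 in each direction by limma, with 6044 genes at an unadjusted p under 0.05. Both arrays had the same dye orientation, so a probe's dye effect was not separated from the genotype, and both lay on the same slide.

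Among flowering-time genes, the florigen gene FT, its transport partner FTIP1 and the FT relatives BFT, TFL1 and TSF were lower in fe-1. FT (AT1G65480) fell by 1.204 ± 0.046 (limma adjusted p = 1.21e-05, lower on both arrays). FT was not well above background in fe-1, so the 2.30-fold higher level in wild type is a lower bound for this probe and processing only. FT lies on the same chromosome as FE, among the 1637 tested genes nearest to it. Its second probe read -0.66. FTIP1 (AT5G06850) fell by 0.55 ± 0.023 (adjusted p = 0.000424). TSF (AT4G20370), also not well above background in fe-1, fell by 0.24 ± 0.081 (adjusted p = 0.0174). In this processing TSF was at least 1.13-fold higher in wild type. With the scanner's processed signals FT read -3.46 and TSF -2.16. In the background fit as planned, with the debris spots kept, FT (-0.61), FTIP1 (-0.30), BFT (-0.71), TFL1 (-0.56) and TSF (-0.10) were lower but not called (adjusted p between 0.365 and 0.686). None of the 5 was called in the series value table, where each had adjusted p = 0.134. CO (AT5G15840), the photoperiod regulator of FT, read 0.00 ± 0.043 (adjusted p = 0.978). SOC1 (AT2G45660) read -0.10 ± 0.14 (adjusted p = 0.270) and GI (AT1G22770) 0.04 ± 0.11 (adjusted p = 0.632). SPL9 fell by 0.40 ± 0.017, NF-YB2 by 0.37 ± 0.17 and SPL4 by 0.36 ± 0.22. Of the 21 floral promoters tested, 1 rose, 7 fell and 13 did not pass, and 1 rose and 8 fell when adjusted over the list alone. The list had a median of -0.09 and shifted down by camera (adjusted p = 0.0103), with adjusted p = 0.786 with an estimated correlation. For this and the lists below, the estimated-correlation test had little power on 1 residual degree of freedom. The main camera p-values rest on the spread across genes and do not measure that between the arrays.

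The floral repressors went both ways. BFT (AT5G62040) fell by 1.51 ± 0.30 (limma adjusted p = 6.31e-05) and TFL1 (AT5G03840) by 1.03 ± 0.048 (adjusted p = 2.26e-05). SVP (AT2G22540) rose by 0.30 ± 0.020 (adjusted p = 0.00592), TEM1 (AT1G25560) by 0.28 ± 0.099 and SMZ (AT3G54990) by 0.22 ± 0.069. FLC (AT5G10140), not well above background in fe-1, read -0.05 ± 0.093 (adjusted p = 0.576). Of 18 repressors, 4 rose, 4 fell and 10 did not pass (5 up and 4 down adjusted over the list alone), and the list did not pass camera (adjusted p = 0.807).

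**Figure D1:**
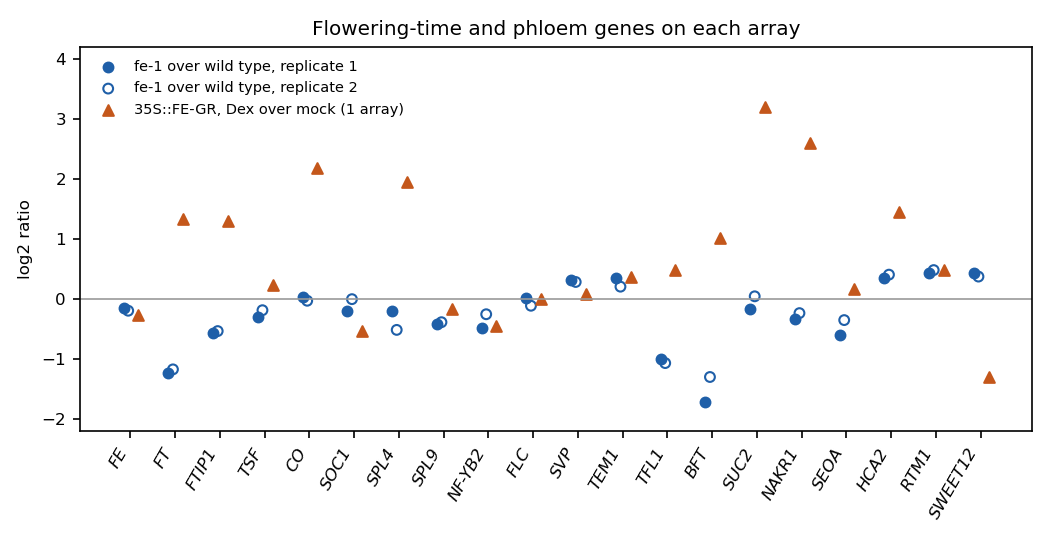
Log2 ratios (y axis) of flowering-time and phloem genes (x axis) on the 2 fe-1 arrays (circles, fe-1 over wild type) and on the Dex array (triangles, Dex over mock). FT lay below 0 on both fe-1 arrays and at 1.34 on the Dex array, and SUC2 lay near 0 in fe-1 and at 3.20 with Dex.

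FE transcript itself was close to wild type, at -0.17 ± 0.031 (limma adjusted p = 0.0429). The call held under 2 of 8 alternative settings, and the mean of its 3 probes read -0.04 (adjusted p = 0.602). The labels do not describe the lesion, so the level of FE checks neither the genotype nor the labels of the fe-1 arrays. FE had a log2 signal of 13.8 with mock on the Dex array, against 9.95 in wild type. A 35S transgene would give this direction. However, signals were not scaled between the comparisons, and CO (10.2 against 7.74) and FLC (8.74 against 6.17) were also brighter with mock. Of 35 phloem genes, 8 rose, 3 fell and 24 did not pass (9 up and 4 down adjusted over the list alone), with a median of 0.00 and no shift by camera (adjusted p = 0.394). RTM1 (AT1G05760) rose by 0.46 ± 0.036, the sucrose exporter gene SWEET12 (AT5G23660) by 0.41 ± 0.048 and the DOF factor gene HCA2 (AT5G62940) by 0.38 ± 0.040. SEOA (AT3G01670), a sieve element occlusion gene, fell by 0.48 ± 0.18, and NAKR1 (AT5G02600) by 0.28 ± 0.068. SUC2 (AT1G22710), the companion cell sucrose symporter gene, read -0.06 ± 0.15 (adjusted p = 0.511). In the xylem and secondary wall list, 0 of 23 genes rose, 4 fell and 19 did not pass (1 up and 5 down adjusted over the list alone). The fallen genes were XCP1 (-0.34 ± 0.033), MYB63 (-0.28 ± 0.015), CESA4 (-0.26 ± 0.0057) and CTL2 (-0.24 ± 0.00091), and the list did not pass camera (adjusted p = 0.134). These genes also read below 0 on the Dex array, of the same dye orientation (-0.42, -0.45, -0.37 and -0.11).

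Root markers were lower in fe-1, led by genes known from root hairs. COBL9 (AT5G49270) fell by 1.305 ± 0.069 (limma adjusted p = 1.04e-05), RHS19 (AT5G67400) by 1.25 ± 0.16, EXPA7 (AT1G12560) by 1.05 ± 0.10 and EXPA18 (AT1G62980) by 0.86 ± 0.068. Of 16 root markers, 1 rose, 10 fell and 5 did not pass (1 up and 11 down adjusted over the list alone). The list shifted down by camera with a median of -0.22 (adjusted p = 3.62e-05), with adjusted p = 0.786 with an estimated correlation. Seed storage and late embryo genes were also lower, 7 of 8 tested (7 adjusted over the list alone), with 0 higher and a median of -0.52 (camera adjusted p = 3.62e-05, and adjusted p = 0.786 with an estimated correlation). The cruciferin genes CRU3 (AT4G28520) and CRA1 (AT5G44120) fell by 2.40 ± 0.98 and 1.93 ± 0.74, with a wide spread between the arrays, and the other probe of CRU3 read -0.71. In the same list the oleosin genes OLEO1 and OLEO2 fell by 0.85 ± 0.35 and 0.70 ± 0.083.

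Photosynthesis genes were slightly higher: 7 of 24 rose, 0 fell and 17 did not pass (7 up adjusted over the list alone). RBCS1A rose by 0.56 ± 0.011, RBCS3B by 0.55 ± 0.011, RBCS2B by 0.50 ± 0.0023 and LHCB1.3 by 0.48 ± 0.094. The same genes read 0.62, 0.66, 0.62 and 0.43 on the Dex array, which had the same dye orientation. A dye effect of these bright probes was therefore not separated from the genotype. These belong to near-identical gene families whose probes can share transcripts, and other probes of RBCS1A, RBCS3B and LHCB1.3 read as low as 0.04, -0.07 and -0.04. The list shifted up by camera with a median of 0.07 (adjusted p = 0.00206), with adjusted p = 0.786 with an estimated correlation. With the scanner's processed signals its median was -0.08 and the call was lost (adjusted p = 0.927), and in the series value table it was -0.045 (adjusted p = 0.923). With median centring the median was 0.385 (camera adjusted p = 1.91e-23), and with the debris spots kept 0.251 (camera adjusted p = 1.04e-16). The call held under 6 of 8 alternatives to the processing, and the size and sign of the shift depended on that choice. The shift ran alongside the lower root markers, whose median was -0.22.

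Stress and defence genes moved in different directions. In the touch and general stress list, 9 of 17 rose, 1 fell and 7 did not pass (11 up and 1 down adjusted over the list alone). TCH4 (AT5G57560), a xyloglucan endotransglucosylase gene induced by touch, rose by 0.93 ± 0.55, ERF6 by 0.56 ± 0.29, TCH2 by 0.54 ± 0.28 and WRKY18 by 0.48 ± 0.099, although the other probe of ERF6 read 0.04. The list had a median of 0.27 (camera adjusted p = 0.000877, and adjusted p = 0.786 with an estimated correlation). Its median was 0.35 on replicate 1 and 0.19 on replicate 2. TCH4, ERF6, TCH2 and WRKY18 were all higher on replicate 1, so their spreads were not independent. In the salicylate defence list, 7 of 14 rose, 1 fell and 6 did not pass (9 up and 2 down adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.0103, and adjusted p = 0.786 with an estimated correlation). WRKY40 rose by 0.75 ± 0.45, PAD3 by 0.57 ± 0.16 and PR2 by 0.45 ± 0.017, while FRK1 fell by 0.37 ± 0.16. Heat shock genes were lower, with 1 of 10 higher, 7 lower and 2 not passing (1 up and 8 down adjusted over the list alone) and a median of -0.25 (camera adjusted p = 0.000604, and adjusted p = 0.786 with an estimated correlation). HSP22 fell by 1.03 ± 0.040, HSP17.4 by 0.53 ± 0.026 and HSP18.2 by 0.50 ± 0.10, while HSP21 rose by 0.46 ± 0.047.

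The jasmonate list held the plant defensin genes, which were lower in fe-1, and JAZ5, which was higher. PDF1.2A (AT5G44420) fell by 1.63 ± 0.11 (limma adjusted p = 8.38e-06), PDF1.2B (AT2G26020) by 1.40 ± 0.17 and PDF1.2C (AT5G44430) by 1.09 ± 0.069, and their related sequences could share probes. JAZ5 rose by 0.49 ± 0.035. Of the 15 jasmonate genes, 8 rose, 5 fell and 2 did not pass (8 up and 6 down adjusted over the list alone). The list's median was 0.21 and its mean -0.15, of opposite sign, and it did not pass camera, whose direction was up (adjusted p = 0.494). In the hypoxia list, 1 of 12 rose, 5 fell and 6 did not pass (1 up and 6 down adjusted over the list alone, camera adjusted p = 0.129). Its fallen genes included HRA1 (-0.77 ± 0.27), LBD41 (-0.43 ± 0.12), PDC1 (-0.37 ± 0.27) and PCO2 (-0.32 ± 0.050).

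Of 15 flavonoid and anthocyanin genes, 2 rose, 7 fell and 6 did not pass (2 up and 8 down adjusted over the list alone, camera adjusted p = 0.0598). F3H fell by 0.52 ± 0.27, FLS1 by 0.52 ± 0.15, MYBL2 by 0.40 ± 0.13 and CHS by 0.34 ± 0.12. On the Dex array, of the same dye orientation, they read -0.64, -0.66, -0.84 and -0.51, so a dye effect was not separated. In the sugar status list, 3 of 19 rose, 4 fell and 12 did not pass, likewise when adjusted over the list alone (camera adjusted p = 0.807). GPT2 rose by 0.51 ± 0.34, BAM5 by 0.45 ± 0.16 (other probe 0.12) and APL3 by 0.34 ± 0.053, and the sucrose synthase gene SUS1 fell by 0.40 ± 0.076, with its other probe at -0.09. In the clock list, 3 of 19 rose and 2 fell (3 up and 3 down adjusted over the list alone, camera adjusted p = 0.807), with BOA at 0.26 ± 0.011, LNK1 at 0.21 ± 0.057 (other probe -0.06), PRR7 at 0.21 ± 0.12 (other probe 0.04) and PRR5 at -0.22 ± 0.0070. Auxin response genes had 2 higher and 1 lower of 16 (1 and 1 adjusted over the list alone, camera adjusted p = 0.476), namely GH3.3 at 0.42 ± 0.18, GH3.5 at 0.23 ± 0.18 and IAA1 at -0.23 ± 0.010. Of 13 cytokinin response genes, ARR16 rose by 0.38 ± 0.021, while ARR7 and ARR5 fell by 0.23 ± 0.10 and 0.18 ± 0.079 (1 up and 2 down adjusted over the list alone, camera adjusted p = 0.347). In the guard cell list, 3 of 11 rose and 0 fell (3 up adjusted over the list alone, camera adjusted p = 0.101), and these were SLAC1 (0.35 ± 0.033), EPF1 (0.24 ± 0.043) and FAMA (0.23 ± 0.10). Of 14 cell division genes, 0 rose and 2 fell (2 down adjusted over the list alone, camera adjusted p = 0.943), STM at -0.27 ± 0.061 (other probe 0.04) and CDKB1;1 at -0.23 ± 0.055.

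**Figure D2:**
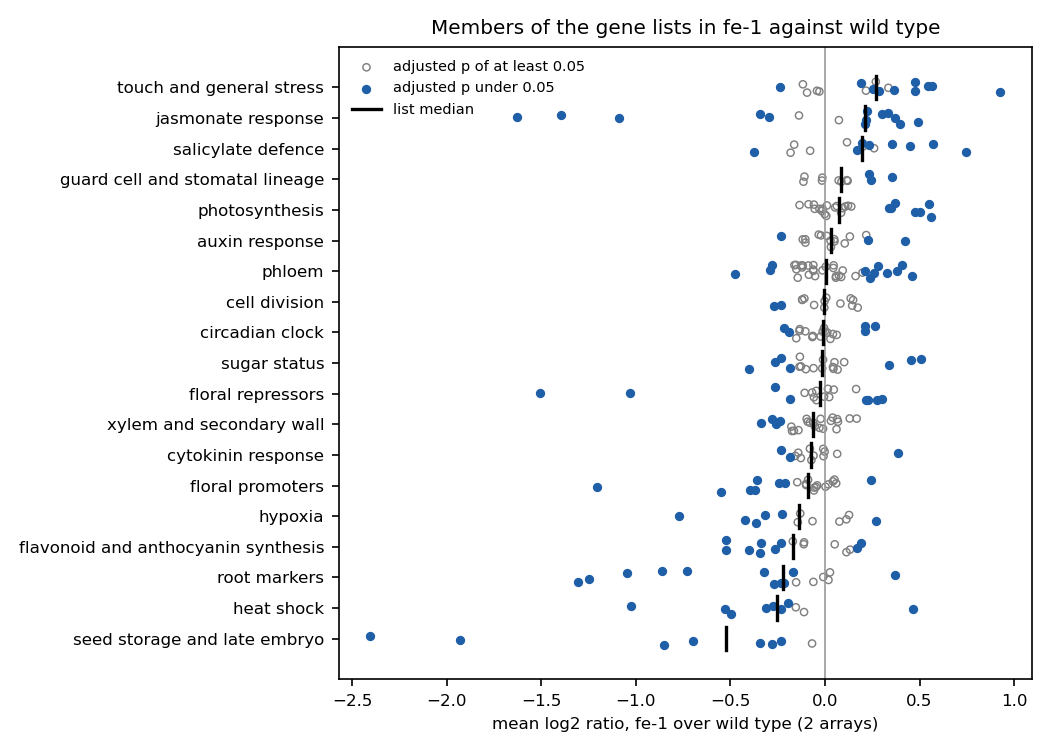
Mean log2 ratio of fe-1 over wild type (x axis, 2 arrays) for each tested member of the 19 gene lists (y axis, ordered by median). Filled points passed the limma test, open points did not, and bars mark list medians, from -0.52 for seed storage genes to 0.27 for touch and general stress.

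The Dex array addresses which transcripts change within 2 h of FE-GR induction. GDH3 (AT3G03910), a glutamate dehydrogenase gene, had its highest ratio and was 141-fold higher with Dex than with mock (7.14, and up to 8.25 on the log2 scale in the series value table). The phosphatase genes PEPC1 (AT1G17710) and PS2 (AT1G73010) followed at 6.22 and 6.16, the nicotianamine synthase gene NAS3 (AT1G09240) at 5.57 and SAL2 (AT5G64000) at 5.12. AT5G20790 was at 5.05, SPX1 (AT5G20150), a gene of phosphate sensing, at 4.99, and MYR1 (AT5G18240), a Myb-related factor gene, at 4.93. AT4G15700 and AT4G15670, members of 1 gene cluster whose related sequences could share probes, were at 4.69 and 4.63. AT3G28270 had the lowest ratio, -4.59 (highest probe -2.58), followed by AT5G62360 (-3.86, highest probe -2.01), AT2G28780 (-3.50), the transporter gene UMAMIT30 (AT4G01450, -3.41) and the nitrate transporter gene NRT1.7 (AT1G69870, -3.03, other probe -1.96). The next lowest were AT1G66180 (-2.99), AT5G10580 (-2.85), KCS12 (AT2G28630, -2.84), DCF (AT3G48720, -2.81) and AT5G24210 (-2.81). Of 20494 genes measured, 733 were at least 2-fold higher and 604 at least 2-fold lower. Without a replicate, and without Dex-treated plants that lack the fusion among these arrays, no part of these ratios can be assigned to FE-GR by test.

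Several flowering and phloem genes were at least 2-fold higher with Dex. CO was at 2.18, SPL4 at 1.94, FT at 1.34, FTIP1 at 1.29 and BFT at 1.02, while SMZ was at -1.02. SUC2 was 9.17-fold higher (3.20), NAKR1 was at 2.60 and HCA2 at 1.44, and SWEET12 was at -1.29. TSF, not well above background with mock, was at 0.23 with a bound of at least 1.17-fold higher, but it read -0.06 with median centring and 2.99 with the scanner's processed signals, so its direction was not settled. FE read -0.26, SOC1 -0.53, TFL1 0.48, GI 0.25, SVP 0.08 and FLC -0.01. Across the processing alternatives FE lay between -0.35 and 0.10, SVP between -0.05 and 0.42 and FLC between -0.07 and 0.20. Their directions were not settled either. At least 2-fold higher were 4 of 21 floral promoters, 1 of 18 floral repressors and 5 of 34 phloem genes, and at least 2-fold lower were 0, 1 and 2 of them. The medians of the promoters (0.10) and the phloem genes (0.02) lay at percentiles 91.1 and 61.7 of 10000 random lists matched on brightness, and that of the repressors (0.30) at percentile 99.98.

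Sugar genes SUS1, SPS4 and SUS4, the last from the hypoxia list, were at 2.88, 1.78 and 1.64, and the probes of SUS4 ranged from 0.09 to 1.64. The jasmonate synthesis gene AOC1 was at 2.73, TCH2 at 1.67 and PAD4 at 1.41 (lowest probe 0.75), while WRKY18 was at -1.67 (other probe -0.73), GH3.3 at -1.49, IAA2 at -1.40, PDF1.2B at -1.46, PDF1.2C at -1.34 and WRKY70 at -1.33. ARR16 was at 1.89, ARR6 at 1.03 and CDKB2;2 at 1.22. The flavonoid list had a median of -0.49, below all 10000 random lists, with 0 of its 14 genes at least 2-fold lower. Other list medians outside the central 95% of their random lists were those of heat shock (-0.51, percentile 0.08), jasmonate (-0.38, percentile 0.08), salicylate defence (-0.29, percentile 0.66), xylem (-0.28, percentile 0.08), auxin response (-0.28, percentile 0.10), root markers (-0.28, percentile 0.43) and touch (-0.24, percentile 0.43). The cytokinin (0.21, percentile 98.6) and sugar (0.27, percentile 99.94) medians were above the central 95% of their random lists. With median centring the cytokinin median was 0.11, at percentile 41.4. Clock (0.09), photosynthesis (0.09), hypoxia (0.14), guard cell (0.05), cell division (-0.14) and seed storage (-0.08, 3 genes measured) medians lay within the central 95%. With median centring the photosynthesis median was 0.61, at percentile 97.9 and so above that range.

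Whether the genes lowered by the mutation are those raised by induction was asked across 19979 genes measured in both comparisons. FT was lower in fe-1 (-1.204, where it was not well above background) and higher with Dex (1.34). RL4 (AT2G18328), a RADIALIS-like gene, was at -1.67 ± 0.17 and 2.42, AT5G18600 at -2.89 and 2.19, and AT2G32550 at -2.35 and 2.105. AT1G24575 (-1.51 ± 0.28 and 1.52), AT1G10380 (-1.36 ± 0.029 and 1.40), the peroxidase gene AT4G26010 (-1.22 ± 0.097 and 2.68) and AT4G00780 (-1.06 ± 0.19 and 1.36) moved likewise. AT1G49570 (1.68 and -1.85) and the glutathione transferase gene GSTU22 (AT1G78340, 1.08 ± 0.13 and -1.71) were higher in fe-1 and lower with Dex. ALDH10A8 and AT1G67865, the lowest in fe-1, were at 0.11 and 0.48 with Dex.

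Over all genes the comparisons were nearly unrelated, with r = 0.024 and rho = 0.11. Of 2262 genes lower in fe-1, 39.4% were higher with Dex, against 48.2% to 52.0% in the central 95% of random lists matched on brightness. Of 1828 genes higher in fe-1, 42.8% were lower with Dex, against 47.6% to 52.0%. Both shares lay below their random lists. With median centring the second share was 26.5%, above its random lists (21.9% to 25.8%), and for the 47 measured genes at least 2-fold lower on both fe-1 arrays the first was 63.8%, against a random median of 51.1%. All 3 arrays had the same dye orientation. Large opposite ratios were more frequent: 6.85% of the genes lower in fe-1 were at least 2-fold higher with Dex, against a random median of 3.54%. Large ratios of the same sign were also more frequent, since 5.39% were at least 2-fold lower with Dex against 2.96%. Of those 47 genes, 8 (17.0%) were at least 2-fold higher with Dex, against a random median of 4.26% and an upper bound of 10.6%. The defensin genes PDF1.2A, PDF1.2B and PDF1.2C, at least 2-fold lower on both fe-1 arrays, were also lower with Dex (-1.29, -1.46 and -1.34). The share of the 47 genes at least 2-fold lower with Dex was not computed.

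**Figure D3:**
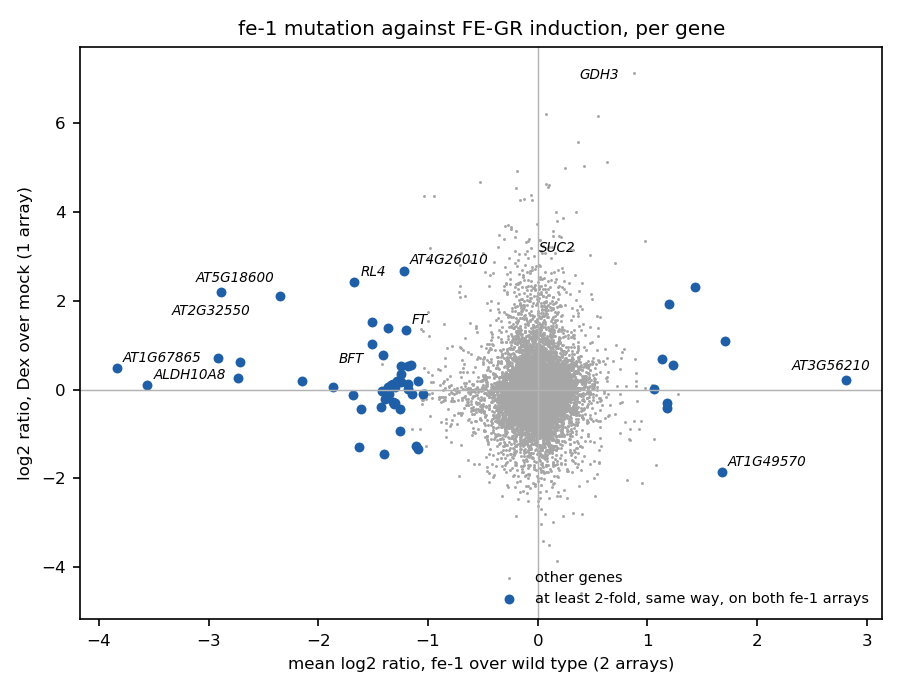
Log2 ratio of Dex over mock (y axis, 1 array) against the mean log2 ratio of fe-1 over wild type (x axis, 2 arrays) for each of 19979 genes. Blue points were at least 2-fold different in the same direction on both fe-1 arrays, and across all genes r was 0.024.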

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

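A signal outside the main measurement came from probes that matched no locus in the reference table and so entered no comparison. Of 4784 such probes measured on both fe-1 arrays, 7 were at least 2-fold lower in fe-1 on both arrays and 0 at least 2-fold higher. Their mean log2 ratios lay between -1.92 and -1.12 (n = 2). The ratios set fe-1 against the wild-type RNA on the same array. No explanation was tested.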

How the results depend on the processing

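Leaving out the debris spots on fe-1 replicate 1, as in the values reported, was chosen after seeing the data. The fit with those spots is the design as written. Over the alternatives with a test, called named genes in fe-1 kept direction and call in 609 cases and kept direction but missed the threshold in 309. Of the 309, 115 were with the series value table, 109 with the debris spots kept and 66 with processed signals, out of 115 called named genes each. Named genes that were not called stayed so in 142 cases, 13 of them with the other sign, and 1 came to pass. Called lists kept their call in 51 cases, lost it in 18 and reversed in 1. Lists not called stayed so in 115 cases and came to pass in 5. With 1 fe-1 array left out, 15 list medians moved beyond the spread between the arrays and 23 did not. On the Dex array, 626 values of named genes stayed close and 372 moved. Seed storage, root marker and heat shock lists passed camera under all 8 alternatives to the processing, with adjusted p up to 0.00325, 0.00245 and 0.0282, but each had adjusted p = 0.786 with an estimated correlation. With 1 residual degree of freedom, the estimated-correlation test could hardly call any list. No paired analysis was possible because each fe-1 log ratio is already a difference within an array, which leaves no further block to fit, and the Dex comparison has 1 array. Slide as a block was not run, and with 1 fe-1 array left out no residual degree of freedom remained, so those values have no test. Signal over background limits dim genes such as FT. Except where named, the cause was not tested.

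The counts of genes changed in fe-1, 1854 higher and 2353 lower, became 161 and 629 with the scanner's processed signals, 0 and 0 with the series value table, 7 and 44 with the debris spots included, and 1011 and 1498 with an offset of 16. Median centring gave 1493 lower, testing every probe 2958 higher, and a required 2-fold change 15 and 78. Genes at least 2-fold different on both fe-1 arrays numbered 35 higher and 187 lower at 1.5-fold, 2 and 11 at 3-fold, 42 and 242 with processed signals, 48 and 228 with the series table, 0 and 8 with the debris spots, and 97 lower with an offset of 16. On a single fe-1 array there were between 21 and 27 higher and between 63 and 91 lower, since only 1 array had to pass. The Dex counts were 1423 and 1655 at 1.5-fold, 343 and 164 at 3-fold, and 1104 and 1221 with the series table. The lower count was 1289 with processed signals and 391 with median centring, which moved the median of all Dex ratios to 0.22.

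Across genes, r and rho between fe-1 and Dex were 0.0635 and 0.120 with processed signals and with the series table, 0.0530 and 0.130 with median centring, 0.0162 and 0.0908 with the mean of all probes, and 0.0427 and 0.118 with the debris spots. With 1 fe-1 array, rho lay between 0.0955 and 0.108. Of genes lower in fe-1, the share higher with Dex turned from below random lists to 63.8% for genes at least 2-fold lower on both arrays, within their random range, and to 11.3% at a required 1.5-fold, above random. Of genes higher in fe-1, the share lower with Dex was 30.0% and 10.3% in the same order. Median centring gave 49.8% for the genes lower in fe-1, below its random lists, and 26.5% for those higher, above its random lists. The debris spots gave 39.5% and 71.4% over 43 and 7 genes, within their random ranges.

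No list passed with an estimated correlation (0) or with fry (0), and 4 did with the series table, where photosynthesis reversed to a median of -0.045. With median centring, the cytokinin median on the Dex array was 0.11, at percentile 41.4 of its random lists, and the photosynthesis median 0.61, at percentile 97.9. The floral promoters missed the threshold with the debris spots (adjusted p = 0.0570), and salicylate and touch with the series table (adjusted p = 0.0960).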

Other observations

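The lists in this part were chosen after seeing the data, as were the tests of neighbouring genes and the phosphate and root hair values without the genes seen first. Genes of the phosphate starvation response stood far above mock on the Dex array. Of 20 such genes, 16 were at least 2-fold higher with Dex and 1 at least 2-fold lower, with a median of 2.97, above all 10000 random lists, whose central 95% lay between -0.14 and 0.16. The galactolipid synthase gene MGD2 was at 4.38, the ribonuclease gene RNS1 at 4.36, the phosphate exporter relative PHO1;H1 at 4.29 and the acid phosphatase gene PAP17 at 3.24, while the phosphate transporter gene PHT1;4 was at -1.26. The fe-1 arrays differed in this list, with a median of 0.19 on replicate 1 and -0.19 on replicate 2, which gives no direction. There 4 genes were higher and 1 lower, RNS1 at -0.95 ± 0.23 (limma adjusted p = 0.000276). The list includes SPX1, PS2 and PEPC1, which were among the highest Dex ratios and prompted it. Without these 3, 13 of 17 were at least 2-fold higher and the median was 2.77. Its place among random lists describes a list written after the array was seen and is no independent test.

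Root hair genes were lower in fe-1, 16 of 18 (17 adjusted over the list alone) with 0 higher and a median of -0.91. The list includes COBL9, RHS19, EXPA7 and EXPA18, which prompted it. Without these 4, 12 of 14 were lower and the median was -0.63. AGP3 fell by 1.61 ± 0.12, RHS13 by 1.39 ± 0.093 and the root hair regulator gene RSL4 by 0.61 ± 0.13. LRX1 (-0.17 ± 0.062, adjusted p = 0.0520) and LRX2 (0.01 ± 0.16, adjusted p = 0.942) did not pass. On the Dex array the list had a median of -0.04 (percentile 32.7). Of 17 genes of inner root tissues and the root cap, 1 rose and 7 fell (1 and 7 adjusted over the list alone), with a median of -0.09 in fe-1 and of -0.27 on the Dex array (percentile 0.33).

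A smaller share of root tissue in the mutant could lower both root hair and inner root genes. Whether it would lower them equally was not tested. The median of hair genes minus that of inner root genes was -0.815 (95% bootstrap interval -1.13 to -0.304, 35 genes), and -0.534 (-1.06 to -0.189) without the 4 genes seen first. Hair genes thus fell further than inner root genes in these lists. The hair list was written after hair genes had been seen to fall, and genes are not independent replicates. A smaller share of root tissue therefore stays open. Shared probes within cell wall protein families would leave the other hair genes near 0, but the median of 11 others was -0.637 (-1.30 to -0.352), and that of 9 without COBL9 and RHS19 was -0.614 (-1.32 to -0.314). A change in root hair genes in fe-1 may be biological, as a hypothesis, since whether hairs differ was not measured. Growth conditions that differed between the genotypes also stay open.

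In fe-1, 4207 genes passed on arrays of 1 dye orientation. A dye effect of the probes would recur on the Dex array with a slope near 1 across called genes. The slope of the Dex ratio on the fe-1 ratio was 0.0505 (-0.0248 to 0.130, 4090 genes), and for changes under 1.5-fold it was 0.212 (0.125 to 0.298, 3812 genes), with 59.5% of those genes of the same sign. This argues against dye, with an effect of equal size on all arrays, as the whole cause. Genes that moved in opposite directions in the 2 comparisons would lower the slope, so its size does not measure the share of dye. For changes under 1.5-fold the interval lay above 0. A partial contribution of dye, to the small changes in particular, may remain and stays open.

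Several of the largest changes lay next to each other, such as AT1G67860, AT1G67865 and AT1G67870 (-2.91, -3.84 and -1.87). Linked background around FE would place changed genes near it, and 7 of the 65 changed genes lay among the 1637 tested genes near FE, 7.92% of all genes (1-sided Fisher's exact p = 0.254, odds ratio 1.41, 95% interval 0.540 to 3.09). All 7 were lower in fe-1, and they include FT, ALDH10A8, AT1G64360, AT1G67860 and AT1G67865. Of the 54 genes at least 2-fold lower on both arrays, 13.0% lay near FE (1-sided Fisher's exact p = 0.132, odds ratio 1.74, 95% interval 0.661 to 3.87). Neither interval excludes an excess or its absence, so linked differences may contribute to these genes and stay open. Chance placement stays open: 7 changed genes had another within 5 tested genes, against a random median of 2, a 95th percentile of 6 and a 99th of 8. No biological explanation was tested.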
